A study of Mus musculus with 6 samples.

How the data were processed

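Gene expression was measured on 6 single-colour Agilent mouse arrays. TEa cells are CD4+ T cells that carry a transgenic receptor (Vα2+Vβ6+). CD45.2+ TEa cells, WT or Irf4 KO, were given on day -1 to CD45.1+ mice that received a Balb/c heart on day 0, and were sorted from the recipients' spleens on day 6. Recipients of cells labelled Irf4 KO were injected on days 0, 3 and 5 either with 400 µg rat IgG or with checkpoint blockade, which combined 200 µg of an antibody to PD-L1 with 200 µg of one to CTLA-4. Recipients of WT cells are labelled as treated with rat IgG, and no dose is stated for them. Each of the 3 groups (WT IgG, Irf4 KO IgG and Irf4 KO blockade) has 2 arrays from independent experiments, called array 1 and array 2 here, array 2 being the one labelled as the repeat.

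Per the labels' protocols, the authors labelled 0.5 µg of total RNA with Cy3 through an amplified cRNA. Per the file headers, spots were read with Agilent Feature Extraction 11.0.1.1 and protocol GE1_1100_Jul11, whereas the submitters' processing notes name version 9.1. The deposited scanner files hold a processed signal, an intensity on a linear scale that is background-subtracted and detrended within each array and not scaled between arrays, together with the median signal and the local background of each spot. The deposited value table holds the same intensity, averaged over the spots of a probe and divided by a single number per array. That ratio was constant within a relative tolerance of 0.001 on each array.

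Each array had 62976 spots, of which 59305 were not controls, for 56605 probes. Spots marked as unusable by the scanner software were dropped, 1234 probes with no usable spot on some array were left out, and 55371 probes were used. The log2 intensity was averaged over the spots of a probe and each array's 75th percentile was subtracted. Probes entered if they were well above background, by the scanner software's own call, on both arrays of at least 1 group. Genes were named through RefSeq accessions in the reference table, which covered 58.3% of probes (22911 gene symbols). Other probes kept their deposited name. The file headers name a genome build other than that of the reference, so no probe positions are given. For genes with several probes the one with the highest mean was kept, which left 28249 genes. limma 3.58.1 in R 4.3.3 fitted the 3 groups together (lmFit and eBayes, 3 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. This is called the all-gene fit. Its model, the gene lists, the rule for named genes and the settings chosen in advance were fixed before the data were examined.

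A further fit was chosen after seeing the data, because the weak probes were brighter on both Irf4 KO IgG arrays, and is called the bright-gene fit. It kept the 8582 genes with a mean log2 intensity of at least 8 (an intensity of 256) and quantile-normalised them among themselves, so that a change in it is relative to the other bright genes. It is 1 of 10 alternatives added at that stage. The others were cyclic loess or the median in place of quantiles, minimums of 7 and 9, a scale set by the median of probes detected on all 6 arrays, the slide row as a block, and the bright-gene fit without each array in turn, with a replicate block and on the 4 arrays compared.

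The preset lists hold 447 distinct genes, of which 7 had no probe under either symbol. The 25 lists cover Irf4 partner and effector transcription factors, co-inhibitory receptors and ligands, Th1 and cytotoxic effector genes, Th2 genes, Th17 genes, T follicular helper genes, regulatory T cell genes, T cell anergy and dysfunction genes, naive and central memory T cell genes, cell cycle genes, glycolysis genes, cholesterol synthesis genes, type I interferon response genes, chemokine receptor and homing genes, apoptosis genes, unfolded protein response genes, T cell identity genes, immediate early and handling stress genes and ribosomal protein genes. They also cover markers of other cells: B cells, plasma cells, monocytes with macrophages and neutrophils, dendritic cells, CD8 T and NK cells, and erythroid cells with platelets. Lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists of a contrast. camera with an estimated correlation and limma's fry were run beside it.

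The named genes are Irf4 first, the 10 highest and 10 lowest log2 fold changes of each contrast among named genes that passed and whose groups did not overlap (the 5 largest at an unadjusted p under 0.05, said not to pass, where fewer than 5 passed), up to 4 members of each list by p with any member that passed, and 25 T cell genes in the contrasts that involve the Irf4 KO IgG arrays. The rule was applied to both fits. Genes that are named outside it are said to be so. A few genes that it names are not reported here, though the counts of changed genes and the list values include them.

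The other settings chosen in advance were normexp background correction of the median signals with an offset of 50, quantile normalisation over all probes, the array median in place of the 75th percentile, no filter, probes detected on all 6 arrays, every probe on its own, the mean of a gene's probes, the 4 arrays compared on their own, eBayes with trend and robust options, a threshold of 0.1, a fold change of at least 2, the deposited value table, a replicate block, and leaving out each array in turn. Mean signals are not among the columns used here, so normexp took median signals. A slide block and a scan block were not run, since all arrays sat on 1 slide and were read in 1 scan.

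The steps were tested on simulated data with each gene's mean over all 6 arrays and its spread in the fit of the 3 groups. In 10 runs 200 genes were changed on the simulated blockade arrays and tested against WT. The all-gene fit recovered 0% of 2-fold, 11.6% of 4-fold, 65.8% of 8-fold and 87.2% of 16-fold changes with 5.51% false calls. The bright-gene fit recovered 76.6%, 97.8%, 98.8% and 100% with 5.57% false calls. With no change simulated, both made 0 calls on average, and camera found the 1 shifted list and 0 others. The camera test was run once, with noise drawn independently for each gene, so it does not test camera on correlated lists. In the bright-gene fit the estimated correlation was 0.81 for the cell cycle list and 0.85 for the interferon list. The number of arrays limits the precision of each value. Prior degrees of freedom were 2.11 in the all-gene fit and 2.68 in the bright-gene fit. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for reading and plotting.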

Results

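The 6 arrays measured gene expression in TEa CD4+ T cells sorted from the spleens of heart transplant recipients. The 3 groups of 2 arrays were WT cells with rat IgG, cells labelled Irf4 KO with rat IgG, and cells labelled Irf4 KO with antibodies to PD-L1 and CTLA-4. The comparisons address what loss of Irf4, a transcription factor induced by T cell receptor signalling, changes in T cells that respond to a graft. They also address what checkpoint blockade changes in cells labelled as lacking it. The share of probes well above background was 37.6% and 40.8% on WT arrays 1 and 2, 39.96% and 34.8% on blockade arrays 1 and 2, but 65.8% and 75.2% on Irf4 KO IgG arrays 1 and 2. Median intensity was 7.36 and 9.08 on the WT arrays, 6.72 and 5.17 on the blockade arrays, and 46.5 and 76.6 on the Irf4 KO IgG arrays. The 75th percentiles used for scaling were 88.6 and 119 for WT, 185 and 301 for Irf4 KO IgG, and 95.6 and 68.0 for blockade. Of 31515 probes dim on both WT arrays, 38.3% were well above background on both Irf4 KO IgG arrays and 0.517% on both blockade arrays. Negative control spots had median intensities between 3.34 and 4.53 on the 6 arrays, and no spot was saturated.

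**Figure D1:**
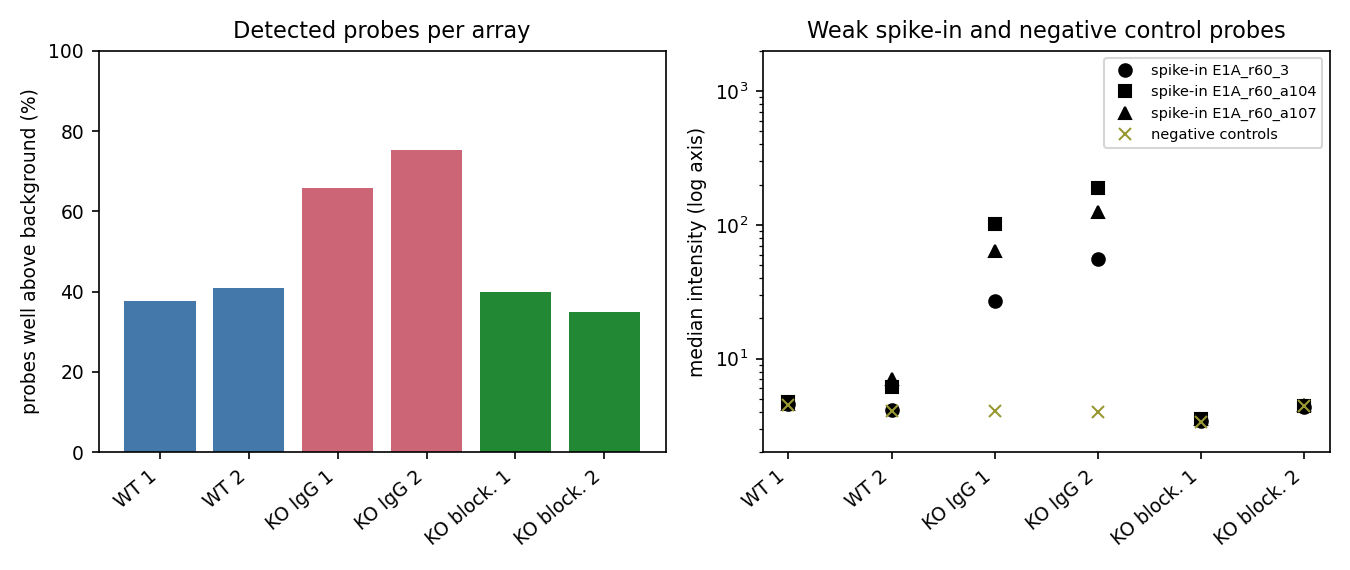
The left panel plots the percentage of probes well above background on each array; the right panel plots the median intensity, on a log axis, of 3 weak spike-in probes and of the negative control probes on each array. The 2 Irf4 KO IgG arrays reach 65.8% and 75.2% while the other 4 lie between 34.8% and 40.8%, and the weak spike-ins rise on those 2 arrays while the negative controls do not.

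Because weak probes were brighter on the Irf4 KO IgG arrays, scaling by the 75th percentile lowered well-measured genes there. Bright genes had a median log2 fold change of -1.05 between Irf4 KO IgG and WT, 1.09 between blockade and Irf4 KO IgG and 0.05 between blockade and WT in the all-gene fit. The account of each comparison therefore leads with the bright-gene fit, which was chosen after the data were seen, and gives the all-gene fit beside it. Over all 28249 genes the median log2 fold change between Irf4 KO IgG and WT was 0.01 with the 75th percentile, -1.65 with the array median, -0.31 with normexp and 0.74 with the median of probes detected on all 6 arrays. Between blockade and Irf4 KO IgG it was -0.11, 1.68, 0.31 and -0.87 with the same 4 scales. Between blockade and WT it was 0.08 with the 75th percentile and 0.20 with the array median. Replacing the 75th percentile by the array median moves every log2 fold change of a contrast by the same amount. The sign changes it gives are therefore not separate evidence on each gene.

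Irf4 (gene identifier 16364, chromosome 13), the gene named in the genotype, gave a higher signal on all 4 arrays labelled Irf4 KO than on the WT arrays before scaling. One of its 2 probes read intensities of 673 and 1068 on WT arrays 1 and 2, 2128 and 3073 on the Irf4 KO IgG arrays, and 2071 and 1703 on the blockade arrays. The other probe read 73.6 and 80.3, then 226 and 221, then 218 and 163. In the bright-gene fit the mean log2 level was 9.71 ± 0.15 (SD, n = 2) in WT, 11.15 ± 0.10 in Irf4 KO IgG and 11.11 ± 0.04 in blockade cells. That is a log2 fold change of 1.44 (SE 0.13, limma adjusted p = 0.0179) and of 1.40 (SE 0.13, limma adjusted p = 0.0182) against WT. The all-gene fit gave 0.39 (limma adjusted p = 0.208) and 1.497 (limma adjusted p = 0.255), and the array median turned the first to -1.28, a fall that passed (adjusted p = 0.00663). The first passed as a rise in 8 of 27 other settings, and its highest adjusted p was 0.361. Where the probes lie relative to the deleted part of the gene is not known here, and a transcript that lacks a deleted exon can still be detected, so the groups are called by their labels.

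Cells labelled Irf4 KO with IgG had higher Eomes, a T-box factor of effector and memory T cells, than WT cells (log2 fold change 2.94, SE 0.16, limma adjusted p = 0.00933 in the bright-gene fit, n = 2 arrays per group). Fam160a1 rose by a log2 fold change of 4.64 (SE 0.15, adjusted p = 0.00141). Penk, which encodes the opioid precursor proenkephalin, rose by 4.73 (SE 0.40, adjusted p = 0.0157) and Spry1, an inhibitor of receptor signalling to Erk, by 2.81 (SE 0.11, adjusted p = 0.00223). Ikzf2, which encodes the transcription factor Helios, rose by 2.19 (SE 0.24, adjusted p = 0.0247), and Tox, a factor linked to T cell exhaustion and follicular helper cells, by 1.11 (SE 0.13, adjusted p = 0.0294). Lower in these cells were Cxcr3, a chemokine receptor of Th1 cells (-1.30, SE 0.12, adjusted p = 0.0194), and the costimulatory receptor Icos (-1.19, SE 0.15, adjusted p = 0.0333). Cxcr5, a receptor that draws T cells to follicles (-1.06, SE 0.16, adjusted p = 0.0492), and Runx3, a transcription factor of effector T cells (-1.04, SE 0.11, adjusted p = 0.0223), were lower too. These 10 genes kept their direction in every other setting run, except Ikzf2, which the array median turned to -0.19, and Tox. Tox was 0.03 in the all-gene fit and passed as a rise in 6 of 27 other settings. The array median turned it to -1.64, which passed (adjusted p = 0.00219), and the all-gene fit gave -0.075 without WT array 1 and -0.029 without Irf4 KO IgG array 2.

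The other large increases between Irf4 KO IgG and WT were Lad1 (3.71), Dusp1 (2.96), Tnfrsf9 (2.81) and Ramp1 (2.71), with the class II genes H2-Eb1 (4.33) and H2-Ab1 (4.27), at limma adjusted p from 0.0143 to 0.0492 in the bright-gene fit. Among the largest decreases were Myo1f (-2.42), Cyp2s1 (-2.40), Adap1 (-2.23), Glrx (-1.95), Gcat (-1.70), Eya2 (-1.61), H2bc18 (-1.61), Adam19 (-1.61) and Tyms-ps (-1.57), at adjusted p from 0.0129 to 0.0492. H2bc18 and Tyms-ps have near-identical relatives, so the copy is uncertain. In all, 168 of 8582 bright genes passed, 98 higher and 70 lower (limma). Of these, 100 (30 higher, 70 lower) also passed in the same direction in the all-gene fit and 0 passed in the opposite one. Fam160a1 passed in 25 of 25 other settings and Eomes in 26 of 26. Spry1 passed in 26 of 27, with an array-median value of 0.32, where adjusted p was 0.230 in a range from 8.0e-05 to 0.230. Cxcr3 passed in 20 of 27 and Ikzf2 in 20 of 26. The number of calls fell whenever 1 array was left out. That held also for the blockade arrays, whose removal changes only the estimate of the spread. It was 6 with the 4 arrays compared on their own. All 168 genes kept their direction in each of these bright-gene fits. The fall in calls therefore does not tell dependence on particular arrays from a less certain estimate of the spread. The array median turned 84 of the 98 higher genes, of which 70 passed as lower.

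**Figure D2:**
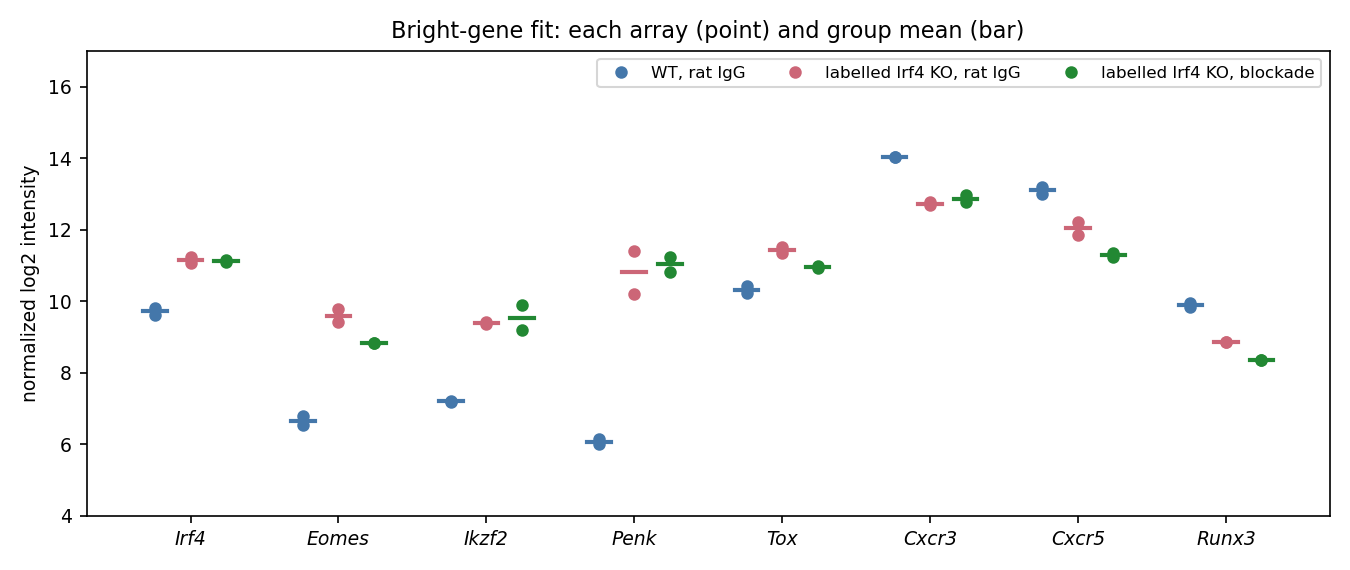
Normalised log2 intensity of 8 genes in the bright-gene fit, with a point for each of the 6 arrays and a bar for each group mean. Eomes, Ikzf2, Penk and Tox are higher and Cxcr3, Cxcr5 and Runx3 lower on the arrays labelled Irf4 KO than on the WT arrays in this fit, and Irf4 itself is higher (mean 9.71 in WT, 11.15 and 11.11 in the others); the array median turns Irf4, Ikzf2 and Tox between Irf4 KO IgG and WT.

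Regulatory T cell genes rose as a list between Irf4 KO IgG and WT, with 9 of 9 measured members positive, a median log2 fold change of 1.35 and a camera adjusted p of 6.0e-06 (adjusted p = 0.386 with an estimated correlation). Ikzf2, Tnfrsf9 (a costimulatory receptor also called 4-1BB; 2.81) and Nrp1 (neuropilin, 2.06, adjusted p = 0.0492) passed, and 6 members passed when adjusted over the list alone. Without Irf4 KO IgG array 2 the median was 0.82, with 8 of 9 positive. T cell anergy and dysfunction genes rose with a median of 0.62, 13 of 13 members positive and a camera adjusted p of 1.9e-06 (adjusted p = 0.386 with an estimated correlation). Eomes, Ikzf2, Tox and Nrp1 passed there, and 7 members when adjusted over the list alone. The median was 0.32 without WT array 1, and 12 of 13 were positive without Irf4 KO IgG array 1. Naive and central memory T cell genes rose with a median of 0.59 (camera adjusted p = 5.4e-04, and adjusted p = 0.501 with an estimated correlation). In that list Bach2, a repressor of effector programmes (1.51), Bcl2 (1.23) and Txk (0.77) passed at adjusted p from 0.0450 to 0.0492, and 10 members when adjusted over the list alone. The medians of these 3 lists were 0.88, -0.36 and -0.49 in the all-gene fit and -0.79, -2.03 and -2.15 with the array median. In the all-gene fit, where bright genes in general fell (median -1.05), camera passed the naive list as lower (adjusted p = 0.0371, and 0.419 with an estimated correlation). By limma 7 of its members were lower there and 1 higher. The regulatory and anergy lists did not pass camera there (adjusted p of 0.339 and 0.544). The medians of the anergy and naive lists were also negative with normexp (-0.01 and -0.11) and among probes detected on all 6 arrays (-0.49 and -0.53). Bach2 and Bcl2 passed as higher in 4 of 26 other settings each and turned to -1.02 and -1.30 with the array median, the second of which passed (adjusted p = 0.00657), while Txk was -0.29 in the all-gene fit. Markers of B cells and of monocytes, macrophages and neutrophils were brighter on the same Irf4 KO IgG arrays. Whether other cells gave part of the rises of these lists and genes was not tested.

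Chemokine receptor and homing genes fell, with 4 of 12 measured members lower (6 when adjusted over the list alone), 0 higher, and 2 higher when adjusted over the list alone. Besides Cxcr3 and Cxcr5 these were the integrin Itgb1 (-1.55, SE 0.19) and the hyaluronan receptor Cd44 (-0.95, SE 0.13), at adjusted p of 0.0333 and 0.0420. The list's median was -0.42 with a camera adjusted p of 0.0186 (adjusted p = 0.482 with an estimated correlation), and this was 0.0734 without WT array 2 and 0.129 without Irf4 KO IgG array 2 (median -0.69 without Irf4 KO IgG array 1). Cell cycle genes had 4 of 27 members positive, a median of -0.89 and 0 members past the threshold by limma (0 when adjusted over the list alone, 12 at an unadjusted p under 0.05). Their camera adjusted p was 0.00159 (adjusted p = 0.696 with an estimated correlation), but 0.409 without WT array 2 (median -0.46) and 0.0672 without Irf4 KO IgG array 1 (median -0.32). T follicular helper genes moved both ways, with Tox higher and Icos, Cxcr5 and Sh2d1a (-1.02) lower, and the same 3 lower when adjusted over the list alone (median -0.00, camera adjusted p = 0.555). Th1 and cytotoxic effector genes had Cxcr3 and the cytokine Tnf (-1.12, adjusted p = 0.0288) lower and the granule gene Nkg7 (1.59, adjusted p = 0.0223) higher, with 4 lower and 1 higher when adjusted over the list alone (median -0.40, camera adjusted p = 0.299). The array median turned Nkg7 to -1.32 (adjusted p = 0.00430). Irf4 partner and effector transcription factors had Irf4 and Irf8 (1.496, adjusted p = 0.0420) higher and Runx3 lower, with 3 higher and 1 lower when adjusted over the list alone (median 0.08, camera adjusted p = 0.346), and Irf8 turned to -1.19 (adjusted p = 0.00995) with the array median. Whether other cells gave part of the rise of Irf8 was not tested. In the all-gene fit, where bright genes in general fell (median -1.05), camera passed the follicular helper, Th1 and Irf4 partner lists as lower. Their medians were -1.08, -1.75 and -0.75 (adjusted p of 0.005, 0.00501 and 0.0389). With an estimated correlation their adjusted p was 0.395 each. By limma 12 of 23 measured Th1 members were lower there and 2 higher.

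Co-inhibitory receptors and ligands had 0 of 7 measured members past the threshold by limma between Irf4 KO IgG and WT in the bright-gene fit (1 at an unadjusted p under 0.05), and 1, Cd200 (0.87), when adjusted over the list alone (median 0.10, camera adjusted p = 0.555). In the all-gene fit 5 of 17 measured members were lower and 1 higher by limma. The median there was -0.62 (camera adjusted p = 0.0389, and adjusted p = 0.608 with an estimated correlation), where bright genes in general fell (median -1.05). Pdcd1, the PD-1 gene, had a log2 fold change of 0.05, Lag3 of 0.18 and Cd274, the PD-L1 gene, of 0.16 in the bright-gene fit. Ctla4 (-0.54) and Nt5e (-0.23) were tested in the all-gene fit alone and did not pass. Tigit, a co-inhibitory receptor, was lower (-3.80, SE 0.79, adjusted p = 0.0147 in the all-gene fit) and well above background on 1 of 2 Irf4 KO IgG arrays, with intensities of 195 and 349 on the WT arrays, 15.2 and 123 on the Irf4 KO IgG arrays and 9.8 and 10.3 on the blockade arrays. Gzmb, the cytotoxic granule protease granzyme B, was lower too (-3.88, SE 0.79, adjusted p = 0.0140), with intensities of 347 and 373, then 32.6 and 97.1, then 3.1 and 10.3. The first call ended without WT array 1 (adjusted p = 0.0536) or 2 (0.0644), in a range from 0.00146 to 0.0644 over 19 settings. The second ended without WT array 1 (0.0592), WT array 2 (0.0547) or Irf4 KO IgG array 1 (0.0590), in a range from 5.0e-04 to 0.0592. Tmprss13 (-6.64), Popdc2 (-5.40), Egln3, an oxygen-sensing hydroxylase (-4.57), and Gpr55 (-4.54) were well above background on 1 of 2 Irf4 KO IgG arrays and fell in each of 19 other settings tested, as Mgarp (-3.66) did in each of 20. Klk1b27 (-3.81), Coro2b (-3.70) and Klk1b24 (at least 5.25-fold lower) complete the 10 lowest genes, at adjusted p from 0.00563 to 0.0162. The call ended for Klk1b27 without WT array 1 (0.0513) and for Coro2b without WT array 1 (0.0603) or 2 (0.0664), which are the highest values over their 19 settings. Havcr2 was not well above background on any array and was not tested.

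Of other genes named in advance, Batf (0.33), Bcl6 (0.20), Il7r (0.59), Izumo1r (0.62), Tbx21 (-0.53), Tcf7 (-0.04), Cd4 (-0.44) and Mki67 (-1.07) did not pass between Irf4 KO IgG and WT in the bright-gene fit. On the all-gene scale Tbx21 (-1.58, adjusted p = 0.0107), Tcf7 (-1.19, adjusted p = 0.0177) and Cd4 (-1.76, adjusted p = 0.00774) passed, falling as bright genes did in general on that scale (median -1.05). Ifng was -2.27 (adjusted p = 0.197), Foxp3 1.03 (0.132), Prdm1 0.36 (0.334) and Il2 -0.02 (0.965), and Foxp3 and Prdm1 were well above background on 1 of 2 WT arrays. The call ended for Tbx21 without WT array 2 (0.0520) and for Tcf7 without WT array 1 (0.0801), WT array 2 (0.0572) or Irf4 KO IgG array 2 (0.0777). The all-gene fit called 16644 of 28249 genes, 8904 higher and 7740 lower (limma), a split that rested on the scaling. It was 3198 higher and 14780 lower with the array median, 1335 and 1932 with normexp, 362 and 9126 among probes detected on all 6 arrays, and 10752 and 789 with the median of those probes. The 10 highest were Svopl (5.87), whose WT arrays were well above background on 1 of 2, and Naa11, Oaz3, Dpysl3, Pdgfd, Mras, Zfp449, Hnf4a, Adam22 and Lratd1, which were not detected on either WT array and were at least 9.51-fold to 26.4-fold higher. The call ended for Naa11 without either WT array (0.0855 and 0.105) or either blockade array (0.0534). It ended for Dpysl3 and Adam22 without any 1 of the WT and Irf4 KO IgG arrays (up to 0.147 and 0.0558), and for Lratd1 without either WT array or Irf4 KO IgG array 2 (up to 0.0724). Naa11 passed in 8 of 19 other settings and Dpysl3 in 10. Leaving out arrays moved the all-gene count to 7633 (WT array 1), 6783 (WT array 2), 10127 and 7724 (Irf4 KO IgG array 1 or 2), with 15145 without either blockade array.

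Some markers of other cells moved with the Irf4 KO IgG group. Of the 3 B cell markers among the bright genes, H2-Ab1 and H2-Eb1, which encode class II molecules that present antigen, passed and Cd74, the invariant chain (3.69, adjusted p = 0.0506), did not, and all 3 passed when adjusted over the list alone. The list's median was 4.27 (camera adjusted p = 6.8e-04, and adjusted p = 0.501 with an estimated correlation). Of 14 B cell markers in the all-gene fit 11 were higher, and Cd74 read 1200 and 5929 on Irf4 KO IgG arrays 1 and 2. The genes S100a9, Hba-a1 and Cd3e were chosen after their values were seen. The neutrophil gene S100a9 read 1333 and 44805 on Irf4 KO IgG arrays 1 and 2, against 238 and 646 in WT and 783 and 3416 with blockade. Hba-a1, a haemoglobin gene, read 1152 and 44583 there, against 127 and 613 in WT and 9121 and 5672 with blockade. T cell identity genes stayed bright on every array, with Cd3e between 28175 and 49031, and their list had a median of -0.02 and a mean of 0.06 while camera gave an upward direction (adjusted p = 0.579). In the all-gene fit, where bright genes in general fell (median -1.05), camera passed this list as lower. Its median there was -1.35 (camera adjusted p = 1.2e-04, and 0.395 with an estimated correlation). Immediate early and handling stress genes rose, with the phosphatase Dusp1 (2.96) and Nfkbia, an inhibitor of NF-κB (0.92), past the threshold and the same 2 when adjusted over the list alone. Their median was 0.46 with a camera adjusted p of 0.0191 (adjusted p = 0.631 with an estimated correlation), which was 0.0559 without WT array 1 (median 0.14) and 0.343 without Irf4 KO IgG array 1 (median 0.15). That median was -0.62 in the all-gene fit, where Nfkbia was -0.39, and was also negative with normexp (-0.23), the array median (-2.29) and probes detected on all 6 arrays (-0.65).

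Other lists did not pass camera between Irf4 KO IgG and WT in the bright-gene fit. Glycolysis genes, which break down glucose, had 2 of 13 members positive (median -0.16, adjusted p = 0.0553) and cholesterol synthesis genes 3 of 14 (median -0.26, adjusted p = 0.0886). Apoptosis genes had Bcl2 higher, with 3 higher and 4 lower when adjusted over the list alone (median 0.11, adjusted p = 0.555). Unfolded protein response genes had Sdf2l1 lower (-0.83, adjusted p = 0.0492), with 2 lower when adjusted over the list alone (median -0.08, adjusted p = 0.555). Type I interferon response genes had 1, Oasl1 (1.69), higher when adjusted over the list alone (median -0.12, adjusted p = 0.863). Ribosomal protein genes had a median of 0.02 over 38 members (adjusted p = 0.592). The Th2 and Th17 lists had 1 bright member each, Gata3 (0.39) and Batf (adjusted p of 0.346 and 0.588). Markers of monocytes, macrophages and neutrophils had a median of 0.46 over 5 members (adjusted p = 0.221) and dendritic cell markers of 0.45 over 2 (adjusted p = 0.555). Plasma cell, CD8 T and NK cell, and erythroid and platelet markers had 1 bright member each, Eaf2 (0.97), Cd8b1 (-0.40) and Hba-a1 (4.52), with adjusted p of 0.434, 0.579 and 0.299. In the all-gene fit, where bright genes fell (median -1.05), camera passed some of these lists. Glycolysis (median -1.37, adjusted p = 5.3e-05), cholesterol synthesis (-1.07, 6.0e-04) and ribosomal protein genes (-1.29, 5.7e-10) were lower. So were interferon (-1.08, 0.00412), apoptosis (-0.79, 0.00631) and unfolded protein response genes (-1.10, 0.00296). Erythroid and platelet markers were higher (3.32, 0.0252). An estimated correlation gave adjusted p of 0.395 to 0.640.

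The highest genes with checkpoint blockade against IgG, in cells labelled Irf4 KO, included several histone genes, which no preset list holds and which were not tested as a group. H3c13 rose by a log2 fold change of 2.78 (SE 0.23, limma adjusted p = 0.0365 in the bright-gene fit, n = 2 arrays per group), H3c3 by 2.51 (SE 0.24, adjusted p = 0.0372), H1f1 by 2.52 (SE 0.22, adjusted p = 0.0365) and H1f3 by 2.19 (SE 0.20, adjusted p = 0.0365). These encode histones that package newly made DNA, and their close relatives make the exact copy uncertain. Cenpw, a centromere protein, rose by 1.92 (SE 0.20, adjusted p = 0.0446), Gcat, an enzyme of threonine breakdown, by 1.89 (SE 0.16, adjusted p = 0.0365) and the non-coding RNA Lockd by 1.55 (SE 0.12, adjusted p = 0.0365). H2bc18 (2.30), H2bc1 (2.11) and Tyms-ps (2.78) rose as well, and all 10 genes passed in the all-gene fit too.

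Cell cycle genes rose as a list with blockade against Irf4 KO IgG, with 27 of 27 measured members positive, a median log2 fold change of 1.70 and a camera adjusted p of 2.8e-10 (adjusted p = 0.632 with an estimated correlation). By limma 0 of the 27 passed over all genes (20 at an unadjusted p under 0.05), while 20 passed when adjusted over the list alone. They include Ccnb1, a mitotic cyclin (2.22, adjusted p = 0.0540), Ccnb2 (3.10, adjusted p = 0.0726), Tyms, which makes thymidylate for DNA synthesis (1.98, adjusted p = 0.0540), and Ccne1 (1.18, adjusted p = 0.0572). The median stayed positive, from 1.62 to 4.15, under the other scalings run. Mki67, a marker of cycling cells, was 1.28 (adjusted p = 0.414), in a range from 0.05 to 2.51 over 12 other settings. The 10 highest genes of the all-gene fit were H2ac4 (4.55), H1f5 (4.43), Cdca3 (4.13), Birc5 (4.09), Nuf2 (4.03), Ccnb2 (4.03), Ube2c (3.97), H2bc7 (3.96), H2aw (3.94) and Ccna2 (3.91), at adjusted p from 0.00581 to 0.0129, and Nuf2 was well above background on 1 of 2 Irf4 KO IgG arrays. The call ended without blockade array 1 or 2 for Nuf2 (0.0523 and 0.0506) and Ccna2 (0.0544 and 0.0520). Type I interferon response genes had 17 of 20 members positive, a median of 0.65 and a camera adjusted p of 0.0102 (adjusted p = 0.740 with an estimated correlation), with 0 members past by limma (5 at an unadjusted p under 0.05) and 0 when adjusted over the list alone. Usp18 was 0.82 and Zbp1, a sensor of nucleic acids, 1.01. That list's adjusted p was 0.0880 without Irf4 KO IgG array 1 and 0.0654 without blockade array 2.

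Naive and central memory T cell genes were lower with blockade than with IgG in the bright-gene fit, with 1 of 19 members positive, a median of -0.43 and a camera adjusted p of 1.8e-04 (adjusted p = 0.631 with an estimated correlation). By limma 0 passed over all genes (11 at an unadjusted p under 0.05), and 8 did when adjusted over the list alone, among them Il7r, the interleukin 7 receptor (-2.10, adjusted p = 0.0814), and Lef1, a factor of naive T cells (-0.82, adjusted p = 0.0679). T cell anergy and dysfunction genes had a median of -0.49 with 1 of 13 positive and a camera adjusted p of 0.00295 (adjusted p = 0.631 with an estimated correlation), and 0 past by limma over all genes or when adjusted over the list alone (5 at an unadjusted p under 0.05). Without Irf4 KO IgG array 1 its median was -0.28 (camera adjusted p = 0.0271). Eomes was -0.77 (adjusted p = 0.0774) and Tox -0.49 (adjusted p = 0.0986). Immediate early and handling stress genes fell (median -0.73, camera adjusted p = 0.00176, and adjusted p = 0.631 with an estimated correlation), with Nfkbia (-0.84), Dusp1 (-1.38) and Zfp36 (-0.73) lower when adjusted over the list alone. T cell identity genes had 0 of 14 positive and a median of -0.29 (camera adjusted p = 0.00295, and adjusted p = 0.632 with an estimated correlation), with 1 lower when adjusted over the list alone. Without Irf4 KO IgG array 2 that adjusted p was 0.124, and without array 1 the median was -0.44. The medians of these 4 lists were 0.71, 0.63, 0.48 and 1.16 in the all-gene fit, where bright genes lay higher with blockade by a median of 1.09. There camera passed the naive, anergy and identity lists as higher, the opposite direction (adjusted p of 0.0211, 0.0279 and 2.0e-04). With an estimated correlation their adjusted p was 0.376, 0.438 and 0.376. The immediate early list did not pass there (camera adjusted p = 0.426). With the array median the 4 medians were 2.502, 2.42, 2.27 and 2.94. They were also positive among probes detected on all 6 arrays (0.76, 0.63, 0.55 and 1.16), with normexp for the naive, anergy and identity lists (0.11, 0.25 and 0.60) and with the bright genes' median for the identity list (0.16). The B cell markers H2-Eb1 (-4.89), H2-Ab1 (-4.43) and Cd74 (-3.11) were all 3 lower when adjusted over the list alone (median -4.43, camera adjusted p = 0.00207, and adjusted p = 0.631 with an estimated correlation).

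The lower genes between blockade and Irf4 KO IgG in the bright-gene fit were Maz (-2.40), Angel1 (-2.04), Peg13 (-1.88), Snrnp35 (-1.72), Mycbp2 (-1.66), Slc49a4 (-1.65), Zfp746 (-1.39), Rb1cc1 (-1.22) and Map11 (-1.17), at limma adjusted p from 0.0365 to 0.0478, and all 9 turned positive with the array median, which turned all 12 lower genes, 9 of them past the threshold. For Maz, Snrnp35 and Slc49a4 1 of 2 probes went this way, for Map11 1 of 3 and for Rb1cc1 3 of 6. In all, 29 of 8582 bright genes passed, 17 higher and 12 lower (unadjusted count 2444), and 23 of them passed in the same direction in the all-gene fit. Without Irf4 KO IgG array 2 there were 302 calls, without Irf4 KO IgG array 1 there was 1, and without any of the other 4 arrays there were 0 by limma (1115 to 2370 at an unadjusted p under 0.05). All-gene fit calls numbered 16612, 7873 higher and 8739 lower. With the array median 14835 were higher and 2645 lower, with normexp 3095 and 1386, among probes detected on all 6 arrays 9291 and 278, and with the median of those probes 1251 and 11097. The all-gene count moved to 10491 and 8883 without Irf4 KO IgG array 1 or 2, 9536 and 10411 without blockade array 1 or 2, and 14962 without either WT array. The 10 lowest genes of that fit were undetected on both blockade arrays, from Svopl (at least 28.0-fold lower) and Zfp939 (at least 25.1-fold) through Naa11, Kctd12b, Gpr182, Gdf5, Tspan15, Hoxc10 and Misp to Olfr481 (at least 11.8-fold), and were among the weak probes that were bright on the Irf4 KO IgG arrays. Naa11 lost this call without either WT array (0.0550) or either blockade array (0.121 and 0.0904).

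The genes named in advance and measured in the bright-gene fit did not pass between blockade and Irf4 KO IgG there. Tbx21, the Th1 master regulator, was 0.67 (adjusted p = 0.106), Batf, an AP-1 factor that pairs with Irf4, 0.64 (0.284), Pdcd1 -0.62 (0.321), Bcl6 -0.72 (0.157), Cd274 -0.44 (0.179), Izumo1r -0.29 (0.174) and Cd4 -0.23 (0.430). Over 12 other settings Batf ranged from 0.088 to 1.199 and Pdcd1 from -1.135 to -0.11. Cxcr3 (0.13), Ikzf2 (0.16), Lag3 (0.16), Tcf7 (-0.14) and Irf4 (-0.04) had adjusted p from 0.496 to 0.866. On the all-gene scale Tbx21 (1.76), Batf (1.95), Cxcr3 (1.43), Izumo1r (1.24), Cd4 (1.16), Irf4 (1.11), Ikzf2 (1.096) and Tcf7 (1.05) were higher at adjusted p from 0.00852 to 0.0407, beside the median of 1.09 for bright genes in general. The call ended for Batf without either blockade array and for Cd4 without either of these or Irf4 KO IgG array 1. It ended for Irf4 and Izumo1r without either Irf4 KO IgG array or blockade array 2, for Tcf7 without Irf4 KO IgG array 2 or either blockade array, and for Ikzf2 without any 1 array but blockade array 1. The adjusted p then lay between 0.0510 and 0.126. Il2 (-1.20, adjusted p = 0.0157) was lower, well above background on 1 of 2 blockade arrays, and Prdm1 was at least 1.096-fold lower (adjusted p = 0.0182). Gzmb was at least 1.103-fold lower and did not pass (adjusted p = 0.105), nor did Ctla4 (0.68), Nt5e (0.63), Foxp3 (0.12), Ifng (-1.32), well above background on 1 of 2 blockade arrays, or Tigit, above it on neither. Both calls ended without Irf4 KO IgG array 2 or blockade array 2, that of Il2 also without Irf4 KO IgG array 1 and that of Prdm1 also without blockade array 1 (adjusted p from 0.0541 to 0.0768). With the array median Il2 turned to 0.59 and Prdm1 to 0.49.

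Blockade-treated cells labelled Irf4 KO, compared with WT cells, shared several of the differences seen with IgG. Penk (4.95, SE 0.40, limma adjusted p = 0.0157), Fam160a1 (3.58, SE 0.15, adjusted p = 0.00609), Spry1 (2.32, SE 0.11, adjusted p = 0.00656), Eomes (2.18, SE 0.16, adjusted p = 0.0125) and Ikzf2 (2.35, SE 0.24, adjusted p = 0.0225) were higher in the bright-gene fit (n = 2 arrays per group). Runx3 (-1.55, SE 0.11, adjusted p = 0.0103), Cxcr5 (-1.82, SE 0.16, adjusted p = 0.0168), Cxcr3 (-1.17, SE 0.12, adjusted p = 0.0237) and Icos (-1.22, SE 0.15, adjusted p = 0.0379) were lower. Crtam, an adhesion receptor of cytotoxic lymphocytes, was higher by 3.01 (SE 0.19, adjusted p = 0.00963) and Nkg7 by 1.82 (SE 0.16, adjusted p = 0.0168). Each of these 11 kept its direction in every other setting run, and Penk, for example, passed in 11 of 27.

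Lad1 (3.60), Ptprs (2.48), Fut7, a fucosyltransferase (2.30), and the fatty acid binding protein Fabp5 (2.11) complete the 10 highest genes between blockade and WT. Cyp2s1 (-2.88), Eya2 (-2.62), Snord17 (-2.12), Adap1 (-2.03), Itpr1 (-1.58), Luzp1 (-1.58) and Man2a2 (-1.54) were among the 10 lowest with Cxcr5 and Runx3. Their adjusted p ran from 0.00825 to 0.0419, and for Man2a2 1 of 2 probes went this way. In all, 86 bright genes passed, 46 higher and 40 lower (limma), of which 31 higher and 22 lower also passed between Irf4 KO IgG and WT, against 0.525 and 0.326 shared by chance if the calls were independent. The contrasts share the WT arrays, so part of this can come from those arrays. The correlation across genes was 0.39, against 0.51 in simulated groups with no change, and the covariance exceeded the simulated one by 0.06. Genes are not independent replicates. The count was 12 and 15 without WT array 1 or 2, 0 by limma without blockade array 1 or 2 (962 and 847 at an unadjusted p under 0.05), and 103 without Irf4 KO IgG array 1 or 2. The all-gene fit called 0 genes (limma, unadjusted count 2159), and its largest changes, none of which passed, were upward in Penk (5.76), Chst3 (at least 12.3-fold), Hbb-b1 (at least 10.96-fold), Stfa3 (5.49) and Glt28d2 (at least 7.59-fold). Downward they were in Tmprss13 (at least 50.7-fold), Gzmb (at least 16.2-fold), Cacna1s (at least 11.8-fold), Tigit (at least 11.8-fold) and Tmem37 (at least 5.58-fold). Without WT array 2 the all-gene fit called 7 genes and without blockade array 1 it called 1.

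Cell cycle genes were higher with blockade than in WT, with 27 of 27 members positive, a median of 1.01 and a camera adjusted p of 5.0e-07 (adjusted p = 0.849 with an estimated correlation), although 0 passed singly by limma, over all genes or when adjusted over the list alone (11 at an unadjusted p under 0.05). Without WT array 1 the median was 0.64, with 23 of 27 positive and a camera adjusted p of 0.00903. Mcm7, a helicase subunit that opens DNA for copying, was 1.01 and Tyms 1.04. Regulatory T cell genes rose, with Ikzf2 past the threshold and 7 when adjusted over the list alone, 9 of 9 positive and a median of 1.25 (camera adjusted p = 2.0e-05, and adjusted p = 0.438 with an estimated correlation). Chemokine receptor and homing genes fell, with Cxcr5, Cxcr3, Cd44 (-0.98) and Itgb1 (-1.39) past the threshold, and 6 lower and 1 higher when adjusted over the list alone. Their median was -0.56 (camera adjusted p = 0.00244, and adjusted p = 0.438 with an estimated correlation). T follicular helper genes fell, with Cxcr5 and Icos past the threshold, and 4 lower and 1 higher when adjusted over the list alone. Their median was -0.33 (camera adjusted p = 0.0372, and adjusted p = 0.752 with an estimated correlation). T cell anergy and dysfunction genes rose, with Eomes and Ikzf2 past the threshold and 4 when adjusted over the list alone. Their median was 0.27 (camera adjusted p = 0.0321, and adjusted p = 0.768 with an estimated correlation). Type I interferon response genes rose, with 18 of 20 positive, 1, Oasl1 (1.67), higher when adjusted over the list alone. Their median was 0.46 (camera adjusted p = 0.00533, and adjusted p = 0.950 with an estimated correlation). T cell identity genes fell slightly (median -0.26, camera adjusted p = 0.0198, and adjusted p = 0.849 with an estimated correlation), with 0 past by limma over all genes or when adjusted over the list alone (5 at an unadjusted p under 0.05). These 7 lists kept the sign of their median under the other scalings run. The camera adjusted p rose for the follicular helper list to 0.0514 and 0.132 without WT array 1 or 2 and to 0.0611 without Irf4 KO IgG array 1 or 2. It rose for the anergy list to 0.226 without WT array 1 (median 0.13) and 0.0611 without Irf4 KO IgG array 1 or 2, and for the interferon list to 0.855 without WT array 2, where its median was -0.01 (0.93 without WT array 1). For T cell identity it rose to 0.0525 and 0.0847 without WT array 1 or 2 and 0.127 without blockade array 2. Erythroid and platelet markers were also higher with blockade than in WT in the all-gene fit, with 8 of 8 positive and a median of 3.55 (camera adjusted p = 2.3e-06, and adjusted p = 0.486 with an estimated correlation), and camera passed without any 1 array. By limma 0 of the 8 passed over all genes (5 at an unadjusted p under 0.05) and 5 when adjusted over the list alone. Their 1 bright member, Hba-a1, was 4.81 in the bright-gene fit, and that list did not pass there (adjusted p = 0.364). In the all-gene fit camera also passed the Th1 and cytotoxic list (8 of 23 positive, median -0.40, adjusted p = 9.5e-04) and the Th17 list (4 of 9, -0.44, 0.0152). It passed the ribosomal protein list too (38 of 39, 0.21, 0.00161). With an estimated correlation their adjusted p was 0.370, 0.514 and 0.883. In the bright-gene fit these lists did not pass (camera adjusted p of 0.603, 0.384 and 0.967).

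**Figure D3:**
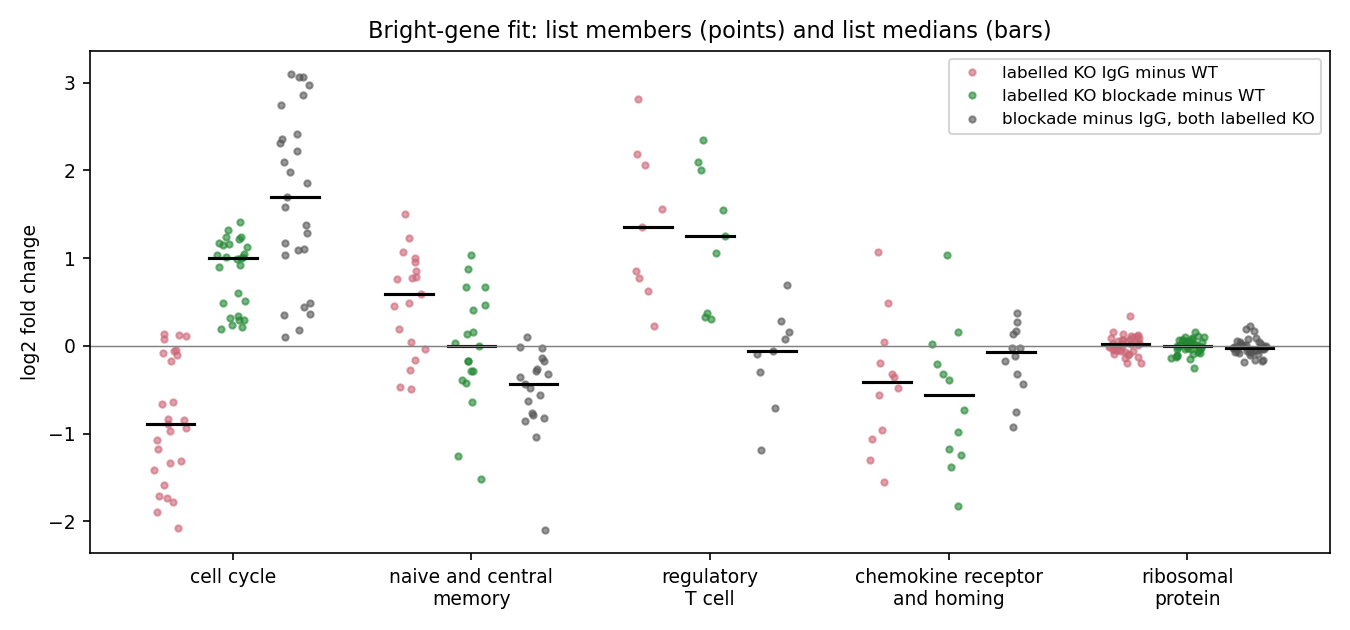
Log2 fold changes in the bright-gene fit of the measured members (points) and their median (bars) for 5 preset lists in the 3 comparisons. All 27 cell cycle genes are above 0 with blockade against Irf4 KO IgG (median 1.70) and against WT (1.01), all 9 regulatory T cell genes are above 0 in both comparisons with WT (1.35 and 1.25), and ribosomal protein genes lie near 0 (0.02 between Irf4 KO IgG and WT); on the all-gene and array-median scales the naive list has the opposite sign in the contrasts that use the Irf4 KO IgG arrays, and on the array-median scale so does the regulatory list between Irf4 KO IgG and WT.

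Whether blockade moved the genes that differed between Irf4 KO IgG and WT back towards WT was asked through their sign. Eomes, for example, was 2.94 higher than WT with IgG and changed by -0.77 with blockade in the bright-gene fit. That change did not pass, and its sign was positive in the all-gene fit. Over 21 other settings of the all-gene fit it ran from -0.77 to 1.94. In the bright-gene fit 78.6% of the 168 genes (132, Wilson 95% interval 71.8 to 84.1) had the opposite sign in blockade against Irf4 KO IgG, with a median of -0.49 for the higher and 0.32 for the lower genes. The Wilson intervals given here treat genes as independent, so they do not measure the spread between arrays. This share includes H2-Ab1 and H2-Eb1, B cell markers that were raised on the Irf4 KO IgG arrays. Because both contrasts share the Irf4 KO IgG arrays, opposite signs arise without any effect: simulated blockade arrays with no change gave 63.4% (60.7 to 67.0 over 50 simulations). The correlation of the contrasts across genes was -0.60 against -0.21 simulated, and their covariance differed from the simulated one by -0.13. Over the all-gene fit the share was 98.8% of 16644 genes (98.6 to 98.9), against 55.0% simulated. The medians were -2.55 and 1.17, the covariance differed from the simulated one by -2.81, and the share includes the rise of weak probes on the Irf4 KO IgG arrays. Leaving out 1 array moved the bright-gene share to 50%, of 10 genes, without WT array 1 and to 100%, of 6 genes, without blockade array 2.

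Arrays of one group were alike in the bright genes, with a Pearson correlation across genes of 0.982 in WT, 0.977 in Irf4 KO IgG and 0.991 in blockade cells, and SDs of the log2 difference of 0.41, 0.46 and 0.28. Over the genes of the all-gene fit the correlations were 0.972, 0.950 and 0.976 and the SDs 0.87, 0.80 and 0.82. The first principal component held 75.3% of the variance there and set the 2 Irf4 KO IgG arrays apart from the other 4. Among bright genes such as Eomes and Cxcr3 the first 2 components held 41.9% and 29.8%. There too the first component set the 2 Irf4 KO IgG arrays apart, at 31.6 and 21.3 against -24.8 to 2.28 on the other 4. The second set the WT arrays (-25.4 and -20.8) apart from the rest (-0.48 to 16).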

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

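The tests of background, of the genotype label, of the weak spike-in probes and of the amount of spike-in mix were chosen only after the result was seen, the genotype test was reworded after related values were known, and the strand test was written before its result.

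A signal appeared in probes that no comparison used, the spike-in control probes. Of 10 such probes, 3 lay at the level of the negative controls on the WT and blockade arrays and above it on both Irf4 KO IgG arrays. On the lower of those 2 arrays the probe E1A_r60_3 read 27.1, E1A_r60_a104 read 101.78 and E1A_r60_a107 read 64.3, where the WT arrays read 4.16 to 7.04 and the blockade arrays 3.44 to 4.54. The strongest spike-in, E1A_r60_1, was not raised, with intensities of 29362 and 35156 against 56015 and 31461 in WT.

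These spike-ins rose together with probes for mouse genes that were dim on the other arrays. A background left in the processed signal would raise the negative controls too, but their level on the Irf4 KO IgG arrays was 0.942 times that on the WT arrays. Because that signal is background-subtracted, the negative controls cannot show whether the scanner or slide background itself was raised. A change of gene expression that follows the genotype label alone is argued against by the blockade arrays, which share the label and whose share of newly bright probes was 0.0135 times that of the Irf4 KO IgG arrays. A change undone by blockade would not raise the 3 weak spike-in probes, which are not probes for mouse genes and rose 9.47 to 26.7 times. It is argued against as the sole cause of both rises, while a part in that of the mouse probes stays open. Of probes dim on the other 4 arrays, 38.5% of RefSeq mRNA, 35.1% of RefSeq non-coding and 40.3% of coordinate-named non-coding probes were bright on both Irf4 KO IgG arrays. Labelled material that binds probes without their own target would raise the weak spike-ins, of which the least raised was 9.47 times its WT level. Because that rise was seen before the test was chosen, it gives no separate support. Another amount of spike-in mix in these 2 samples is argued against as the cause of that rise by the other 7 spike-in probes, which had a median of 0.858 times their WT level (0.738 to 1.602). Whether binding is regardless of gene or strand stays open, since both strands were bright at 14.9% of loci (46 of 308), where 14.8% was expected of independent strands, between the bounds set in advance.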

How the results depend on the processing

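The bright-gene fit, its variants, the scale from probes detected on all 6 arrays and the slide row block were chosen only after the data were seen, and the other settings were fixed in advance. Low signal limits the all-gene results, since probes near background were raised on both Irf4 KO IgG arrays. The number of arrays limits the bright-gene results, whose counts moved when any 1 array was left out. The array median and the 75th percentile differ by a single number per array. Changing between them moved all log2 fold changes of a contrast by the same amount. Between Irf4 KO IgG and WT this took the median over all genes from 0.01 to -1.65. The array medians were 46.5 and 76.6 on the Irf4 KO IgG arrays and 7.36 and 9.08 on the WT arrays. The sign changes with the array median are therefore a single offset. Which other settings changed a result through probes near background was not tested, nor was the cause of their changes. Slide and scan blocks were not run, since 1 slide and 1 scan held all arrays. With groups of 2 arrays, leaving out 1 leaves a lone array that is assumed to vary like the other groups.

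Between Irf4 KO IgG and WT the all-gene count of 16644 became 3267 with normexp, 6075 with quantile normalisation, 10597 with no filter, 9488 among probes detected on all 6 arrays and 168 in the bright-gene fit. Between blockade and Irf4 KO IgG the count of 16612 became 4481, 6527, 9569 and 29 with normexp, quantile normalisation, probes detected on all 6 arrays and the bright-gene fit. Between blockade and WT the count of 0 became 74 with normexp, 63 among probes detected on all 6 arrays, 391 with trend and robust options, 5 at a threshold of 0.1 and 86 in the bright-gene fit. Leaving out single arrays gave 6783 to 15145, 8883 to 14962 and 0 to 7. In the bright-gene fit the count of 168 became 298 with the bright genes' median, 92 from a minimum of 9, 23 with a replicate block and 6 on the 4 arrays compared. The count of 29 became 830, 55, 18 and 0 with the bright genes' median, minimums of 7 and 9 and the 4 arrays compared. The count of 86 became 134 with the median and 54 with a replicate block. Without single arrays these 3 counts ranged from 6 to 93, from 0 to 302 and from 0 to 103.

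The share with the opposite sign under blockade, 98.8%, was 97.7% with normexp, 98.3% with quantile normalisation, 99.5% with the array median, 99.02% with no filter, 98.5% among probes detected on all 6 arrays and with their median, 98.5% on the 4 arrays compared, 98.4% at a threshold of 0.1 and 78.6% in the bright-gene fit. It ranged from 97.54% to 99.2% without single arrays. In the bright-gene fit the share was 85.6% from a minimum of 7 and ranged from 50% to 100% without single arrays. Lists past the threshold in the all-gene fit, 16 between Irf4 KO IgG and WT, became 8 with quantile normalisation, 8 among probes detected on all 6 arrays, 7 in the bright-gene fit and 0 with an estimated correlation, and ranged from 13 to 17 without single arrays. Between blockade and Irf4 KO IgG 16 became 7 with normexp, 2 with quantile normalisation, 5 among probes detected on all 6 arrays, 7 in the bright-gene fit and 0 with an estimated correlation, with a range of 11 to 17. Between blockade and WT 10 became 6 among probes detected on all 6 arrays, 0 with an estimated correlation and 0 with fry, with a range of 6 to 12. In the bright-gene fit 7 lists in each contrast became 0, 0 and 0 with an estimated correlation and 3, 0 and 1 with fry, and ranged from 6 to 7, 6 to 8 and 4 to 8 without single arrays.

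Genes named from the all-gene fit kept their direction and their side of the threshold in 1137 other values, against 72 that lost the call, 71 that gained it and 73 that changed sign. Without single arrays these numbers were 500, 64, 8 and 10. For genes named from the bright-gene fit they were 1495, 603, 19 and 52, and 563, 371, 11 and 15 without single arrays.

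Sign changes from the all-gene fit between Irf4 KO IgG and WT, as log2 fold changes, were as follows. Quantile normalisation gave Batf 0.34, Bcl6 0.21, Foxp3 -0.12, Il7r 0.59, Izumo1r 0.62, Lag3 0.025, Nt5e 0.11, Pdcd1 0.06 and Prdm1 -1.13. The bright-gene fit gave Batf 0.33, Bcl6 0.20, Cd274 0.16, Il7r 0.59, Izumo1r 0.62, Lag3 0.18 and Pdcd1 0.054. The median of probes detected on all 6 arrays gave Cd274 0.11, Ctla4 0.19, Il2 0.71, Il7r 0.20, Lag3 0.08 and Nt5e 0.50. Normexp gave Foxp3 -0.037, Nt5e 0.092 and Prdm1 -0.47. The array median gave Foxp3 -0.64, Ikzf2 -0.19, Irf4 -1.28, Prdm1 -1.30 and Tox -1.64. The deposited value table gave Il2 0.17. Without single arrays the values ranged over Il2 -0.11 to 0.08, Il7r -1.20 to 0.14, Nt5e -0.76 to 0.30 and Tox -0.075 to 0.14.

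Between blockade and Irf4 KO IgG the all-gene fit's signs changed as well. Normexp gave Bcl6 -0.18, Eomes -0.28, Gzmb 0.14, Pdcd1 -0.02, Prdm1 0.30 and Tigit 0.28. Quantile normalisation gave Bcl6 -0.72, Cd274 -0.14, Cd4 -0.22, Eomes -0.73, Irf4 -0.035, Izumo1r -0.30, Pdcd1 -0.62, Prdm1 0.42, Tcf7 -0.14, Tigit 0.62 and Tox -0.48. The bright-gene fit gave Bcl6 -0.72, Cd274 -0.44, Cd4 -0.23, Eomes -0.77, Irf4 -0.038, Izumo1r -0.29, Pdcd1 -0.62, Tcf7 -0.14 and Tox -0.49. The median of probes detected on all 6 arrays gave Bcl6 -0.37, Cd274 -0.43, Ctla4 -0.079, Eomes -0.61, Foxp3 -0.64, Nt5e -0.13, Pdcd1 -0.22 and Tox -0.093. The deposited value table gave Eomes -0.029 and Foxp3 -0.057. The array median gave Gzmb 0.02, Ifng 0.47, Il2 0.59, Il7r 0.78, Prdm1 0.49 and Tigit 1.24. Without single arrays the values ranged over Foxp3 -0.60 to 0.84, Ifng -3.37 to 0.73 and Tigit -1.72 to 0.61.

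For genes of the bright-gene fit between Irf4 KO IgG and WT signs changed in these settings. The array median gave Ikzf2 -0.19, Irf4 -1.28, Tox -1.64, Irf8 -1.19, Nkg7 -1.32, Nrp1 -0.66, Txk -1.96, Bcl2 -1.30, Bach2 -1.02 and Nfkbia -2.05. The bright genes' median gave Pdcd1 -0.12. Cyclic loess gave Tcf7 0.001. The mean of a gene's probes gave Txk -0.29 and Nfkbia -0.39. The deposited value table gave Txk -0.10 and Nfkbia -0.20. The all-gene fit, no filter, every probe on its own, probes detected on all 6 arrays, the 4 arrays compared, trend and robust options, a threshold of 0.1, the replicate block and the slide row block gave the same -0.29 for Txk and -0.39 for Nfkbia. Without single arrays the values ranged over Batf -0.23 to 0.89, Bcl6 -0.17 to 0.57, Il7r -0.15 to 1.33, Lag3 -0.42 to 0.77, Mki67 -2.30 to 0.16, Pdcd1 -0.46 to 0.57 and Tcf7 -0.26 to 0.18.

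For genes of the bright-gene fit between blockade and Irf4 KO IgG signs changed likewise. The array median gave Maz 0.35, Angel1 0.67, Peg13 0.82, Snrnp35 0.95, Mycbp2 1.04, Slc49a4 0.996, Zfp746 1.29, Rb1cc1 1.41 and Map11 1.66. The mean of a gene's probes gave Snrnp35 0.054 and Map11 0.32. The bright genes' median gave Cd4 0.16, Irf4 0.11, Izumo1r 0.25, Tcf7 0.054, Dgkz 0.006, Zap70 0.035 and Cd247 0.006. Without single arrays the values ranged over Cd4 -0.47 to 0.01, Ikzf2 -0.20 to 0.52, Irf4 -0.11 to 0.034, Lag3 -0.16 to 0.49 and Tcf7 -0.36 to 0.085. If the repeat arrays shared a source of variation, array 1 minus array 2 would correlate between groups across genes. The correlations were -0.06 (WT and Irf4 KO IgG), -0.19 (WT and blockade) and 0.11 (Irf4 KO IgG and blockade) in the all-gene fit, and 0.01, -0.20 and 0.03 in the bright-gene fit. Genes are not independent replicates.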

Other observations

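The tests of the genotype labels were chosen only after the Irf4 signal was seen, those of a single wrong label were reworded after earlier forms had been run, and those of other-cell markers were written before their results.

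Some further values belong to members of the preset lists. In the bright-gene fit Cd200, a ligand that restrains myeloid cells, was 0.97 with blockade and 0.87 with IgG against WT, so about as high without blockade, and higher in both when adjusted over the list alone. Against Irf4 KO IgG, Sdf2l1 was 0.90 with blockade, the 1 member of the unfolded protein response list that was higher when adjusted over the list alone. Camera gave this list and the apoptosis list an upward direction at an adjusted p of 0.833. The apoptosis list had a median of 0.08 and a mean of -0.04, and the unfolded protein response list a median of -0.03 and a mean of 0.02. The glycolysis genes Tpi1 (0.82) and Pgk1 (0.68) were the 2 of their list higher when adjusted over the list alone (median 0.16, camera adjusted p = 0.117). Against WT, camera gave an upward direction to the naive list (median -0.00, mean -0.04, adjusted p = 0.961) and to the glycolysis list (median 0.00, mean -0.01, adjusted p = 0.967). It gave a downward direction to the unfolded protein response list (median 0.02, mean -0.09, adjusted p = 0.833).

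Markers of B cells and of monocytes, macrophages and neutrophils were brighter on both Irf4 KO IgG arrays. Over these 2 arrays plasma cell, dendritic cell, and CD8 T and NK cell markers lay within the range of random lists (percentiles 67.37, 73.06 and 90.81), and erythroid and platelet markers above it (2.41, percentile 99.92), though not on array 1 alone (92.68). On array 2 alone the CD8 T and NK cell markers lay above it (1.51, percentile 98.35). The rise shared by all dim probes is argued against as the whole cause, since the median rise of 16 B cell markers (3.06) lay at percentile 100 of 10000 random lists of like level, as did that of 21 monocyte, macrophage and neutrophil markers (1.81, percentile 100), while T cell identity genes lay at percentile 39.1. B cells carried into the sorted cells are consistent with the B cell markers, which were at percentile 100 on each of the 2 arrays, with Cd79b at 499 and 2690 and Cd74 at 1200 and 5929. The sort gate on Vα2, Vβ6, CD45.2 and CD4 would remove such cells, so that their RNA or adhering cells would be needed, which was not tested. Erythroid and platelet markers were also higher on the blockade arrays than on the WT arrays (1.30, percentile 100), where the B cell list was not (0.19, percentile 83.7), although Cd79b read 267 and 275 there against 43.7 and 51.8 in WT. Between blockade and Irf4 KO IgG the erythroid and platelet list had a median of 1.16 and a mean of 0.11 in the all-gene fit (camera adjusted p = 0.875).

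Irf4 read higher on all 4 arrays labelled Irf4 KO than on WT arrays before scaling. A single wrong genotype label is argued against as the cause. Among the WT and blockade arrays the lowest blockade array lay above the highest WT array on both probes and each of 4 scales, by at least 0.673, more than the larger SD of the 2 groups each time. The level of the Irf4 KO IgG arrays against WT depended on the scale, with a smallest gap of -0.181 on the 75th percentile scale and both arrays below WT on the array median. If 1 of those 2 arrays had the other genotype, they would differ from each other about as blockade does from WT, but they differed by at most 0.288 times as much, as the mean of both probes. That takes the Irf4 level to follow the genotype alike in both treatments. Labels exchanged between whole groups stay open, because the log2 fold change of 1.40 between blockade and WT would need a probe known to lie in the deleted part of the gene. A transcript that is made from the deleted gene and still binds the probes may give the same values, so that these tests do not tell the genotype.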
